A study of Lactococcus lactis with 2 samples.

How the data were processed

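RNA was measured by sequencing in 2 libraries of Lactococcus lactis strain F44, a lactic acid bacterium. One library came from cells held for 1 h in medium of pH 4.0 and the other from cells at pH 7. Per the labels' protocols, the cells were taken in mid-logarithmic growth, total RNA was treated with DNase, and libraries followed standard Illumina protocols. Whether the libraries keep strand is not given in the sources used here. With 1 library per condition, the spread between cultures cannot be estimated, and no p-value is computed here.

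Per the submitters' processing notes, the tools used were CASAVA 1.8.2, Trimmomatic 0.30, Bowtie 0.12.7, RSEM and edgeR 3.4.2. The notes give no settings, and the genome build is not given in the sources used here. Per the file headers, the deposited tables hold expected counts, which are read counts estimated by a model that can divide a read between similar gene models. The authors also deposited TPM and FPKM for each library, together with gene model lengths and effective lengths. TPM summed to the same total in both libraries, within rounding. Among models of 1000 bases or more, the median difference between coding length and effective length was 63.9 bases in the pH 4 library and 65.6 bases in the pH 7 library. One table also gives the authors' log2 fold change, p-value and FDR for 641 of 2212 gene models, all with p under 0.05. A second table gives the same values for the 418 models with FDR under 0.05. From its sign against the counts, the authors' fold change is pH 7 over pH 4 in all 641 models, so it is reversed here before it is compared. The authors' p-values come from 1 library per condition, and the dispersion behind them is not given in the sources used here. Their ranks and FDR values imply that 2090 models were tested.

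The deposited feature file lists 2212 gene models predicted with Glimmer3 on one sequence named DYH, with coordinates from 358 to 2397122 that count from 1. The models carry an identifier and no gene name or product, and every length is a multiple of 3, so lengths are coding lengths. For 1 model the table gives 1455 bases and the feature file 897. A reference table of another strain of the species (14B4, assembly ASM317683v1) was searched by identifier, and 0 of the 2212 models matched. No gene name is therefore given. The 36 functional gene lists fixed before the data were examined had no matched member, and their medians were not computed. The rule fixed for named genes asked for a symbol or product and so named none. Instead, 4 model identifiers were chosen after their values were seen. They are those with the highest and lowest ratios among loci of a single model outside a duplicated segment, with mean abundance at or above the median.

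Each library was scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, on expected counts rounded to whole numbers. Ratios are log2 of pH 4 over pH 7 with a pseudocount of 0.5 counts, shared between the libraries in proportion to their size. Models with at least 10 counts in 1 or both libraries were kept. A model or locus counts as higher or lower when its ratio is at least 2-fold and its 95% interval excludes equality. The interval is the exact conditional binomial (Clopper-Pearson) interval of the 2 counts. It covers counting error only, since reads without molecular identifiers are not independent molecules and cultures were not repeated. Shares of a library's counts have 95% Clopper-Pearson intervals with the same limit. Python 3.11.15 with scipy 1.17.1 was used for these steps.

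After the data were seen, gene models on the same strand that overlap over at least 50% of the shorter were summed into 1 locus. A segment listed in 2 copies was counted once. Together these steps gave 2034 loci, of which 1964 were kept. Blocks and runs were also defined after the data were seen. A block is a stretch of at least 3 consecutive kept loci on 1 strand, all called the same way, with gaps of up to 300 bases. A run is a stretch of at least 3 consecutive same-strand loci with gaps of up to 100 bases, whatever their calls. Stretches that held a locus not kept were left out of the runs.

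The calling step was tested on simulated data with counting error alone for all 2212 models. It called 98.0% of genes simulated with a 4-fold difference and 99.0% of those with a 3-fold difference in the right direction, and 9 of 1875 unchanged genes. The true ratio lay inside 95.4% of the intervals. The simulated counts followed the error model that the interval assumes, so this checks the calculation and not the real error. Scaling, reads divided between overlapping models and 2-fold differences were not simulated. Alternatives tried were DESeq2 1.42.0 size factors, library totals and the upper quartile for scaling, other filters, a pseudocount of 5, the deposited TPM and fold changes, and a 4-fold threshold.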

Results

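RNA sequencing compared 1 culture of Lactococcus lactis strain F44 held for 1 h in medium of pH 4.0 with 1 control culture at pH 7. The sample labels list the control as untreated and give no holding time for it. Effects of the change of medium or of the added time can therefore not be told apart from those of pH. Lactococcus lactis is a fermenting bacterium that acidifies its own medium by releasing lactate. The pH 4 library held 3461353 expected counts over the 2212 gene models and the pH 7 library held 2425138. Median depth was 360.5 expected counts per gene model at pH 4 and 239 at pH 7. In all, 94 models were listed at 0 at pH 4, 104 at pH 7 and 68 in both. With a floor of 3 counts, a count of 0 allows an abundance of up to 0.854 CPM (counts scaled to TMM library size) at pH 4 and 1.26 CPM at pH 7. There were no replicates, so every difference below describes these 2 libraries and has no replicate check.

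The transcriptome of the acid-treated culture differed widely from that of the control, in both directions. Of the 2077 gene models kept, 465 (22.4%) were at least 2-fold higher at pH 4 and 473 (22.8%) were at least 2-fold lower, with counting intervals that excluded equality. The remaining 1139 models were within 2-fold or had intervals that included equality. The median log2 ratio was 0.02, with quartiles of -0.90 and 0.91. TMM scaling assumes that most models do not change, so ratios are relative and a change in total mRNA would not show. The near-equal numbers in both directions follow in part from this scaling. Upper-quartile scaling gave 548 models higher and 401 lower. The median width of the counting interval was 0.47 on the log2 scale. In the authors' deposited table, 418 models passed an FDR of 0.05, with 201 higher at pH 4 and 217 higher at pH 7.

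Many gene models were not independent measurements. Overlapping models on the same strand made up 199 of the 2212 models, in 99 loci, and 94 of the 98 loci with exactly 2 models shared a start or an end coordinate. A segment of 97.8 kb was also listed in 2 copies in opposite orientation, from 812612 to 910377 and from 1517823 to 1615588. In all 78 pairs of gene models at mirrored positions, the members had expected counts identical to each other in each library. Of these pairs, 65 had 10 counts or more in 1 or both libraries. The copies held 81 and 95 gene models, so some models had no mirrored partner. The segment was located through opposite-strand models of equal length and equal counts, so the equality follows in part from the search. Sequence was not examined here. With overlapping models summed and the segment counted once, 424 of 1964 loci (21.6%) were at least 2-fold higher at pH 4 and 432 (22.0%) were at least 2-fold lower. Values below refer to these loci unless gene models are named, and for loci the duplicated segment is given by its first copy.

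The lower side reached further than the higher side. At pH 4, 137 loci were at least 4-fold higher and 152 at least 4-fold lower. At 16-fold these numbers were 12 and 51, and at 32-fold they were 3 and 32. These numbers do not count separate changes, because many of the lowest loci are neighbours. All members of the blocks that start at 394628, 413106, 903983 and 1785813, described below, were over 32-fold lower. Abundance across loci had a Pearson r of 0.79 (log2 CPM) and a Spearman rho of 0.79 between the libraries. These are correlations across loci, which are not independent replicates.

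**Figure D1:**
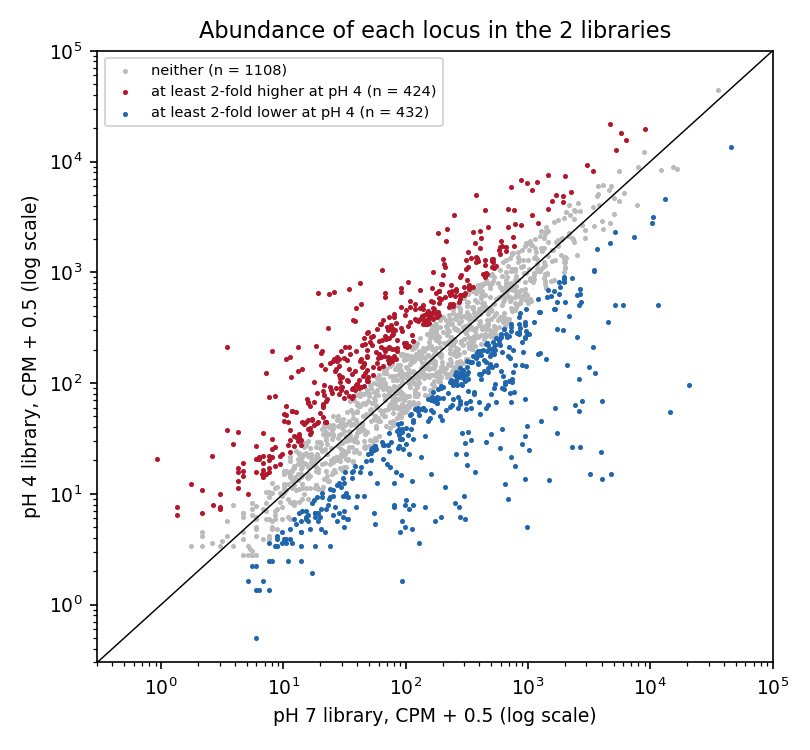
Abundance of each of 1964 loci in the pH 7 library (x axis) and the pH 4 library (y axis), in CPM + 0.5 on log scales, with 1 point per locus and the line of equality. The 424 loci at least 2-fold higher at pH 4 and the 432 at least 2-fold lower lie on both sides of the line over the whole range, and the farthest points lie on the lower side.

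The share of all counts taken by the loci called was as follows. These loci were chosen by their direction, so the direction of each share follows from the choice. The loci at least 2-fold lower at pH 4 took 37.7% of the counts at pH 7 (95% Clopper-Pearson interval 37.7 to 37.8) and 8.40% at pH 4 (8.37 to 8.42). Loci at least 2-fold higher at pH 4 took 10.7% of the counts at pH 7 (10.6 to 10.7) and 37.0% at pH 4 (36.9 to 37.0). Among the 100 most abundant loci of the pH 7 library, 41 were at least 2-fold lower at pH 4 and 9 were at least 2-fold higher, with a median log2 ratio of -0.72. Among the 100 most abundant of the pH 4 library, 39 were at least 2-fold higher at pH 4 and 6 were at least 2-fold lower, with a median of 0.71. Ranking by the abundance in 1 library favours loci that are higher there, so neither list shows a direction for abundant loci in general. Only 3 loci were among the 10 most abundant in both libraries, and 55 were among the 100 most abundant in both. The 10 most abundant loci took 17.8% of the counts at pH 4 (17.8 to 17.9) and 19.4% at pH 7 (19.3 to 19.4).

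Loci that were lower at pH 4 were often neighbours on the same strand. They formed 49 blocks of at least 3 loci, holding 221 of the 432 lower loci. A block holds only loci called the same way by definition, so it can end inside a longer run of close neighbours. The most abundant block at pH 7 spanned 1010245 to 1013851 on the plus strand with 3 loci. It took 6.01% of the counts at pH 7 (5.98 to 6.04) and 1.84% at pH 4 (1.83 to 1.85), a log2 ratio of -1.75 (-1.76 to -1.74). This block opens a run of 6 loci up to 1017330, with 3 members lower, 1 higher and a median log2 ratio of -0.34. The block with the next greatest loss of abundance spanned 413106 to 418481 on the plus strand with 4 loci. It took 4.06% of the counts at pH 7 (4.03 to 4.08) and 0.0192% at pH 4 (0.0178 to 0.0207). This was a 217.7-fold lower abundance, a log2 ratio of -7.77 (-7.88 to -7.66), and its members lay between -8.07 and -6.65.

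A block of 5 plus-strand loci upstream of it, from 394628 to 399358, had a log2 ratio of -7.05 (-7.23 to -6.87). It held 23227 counts at pH 7 and 258 at pH 4. Its member DYH_g0386, a coding region of 1338 bases at 396503 to 397840 on the plus strand, had the lowest ratio of the loci of 1 model outside the duplicated segment with at least median abundance. Its TPM was 3139 at pH 7 and 9.86 at pH 4, a log2 ratio of -8.34 (-8.79 to -7.97). The next lowest was DYH_g0398, a coding region of 1566 bases at 413728 to 415293 on the plus strand, inside the block of 4 loci. Its TPM was 8102 at pH 7 and 31.0 at pH 4, a log2 ratio of -8.07 (-8.29 to -7.87).

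**Figure D2:**
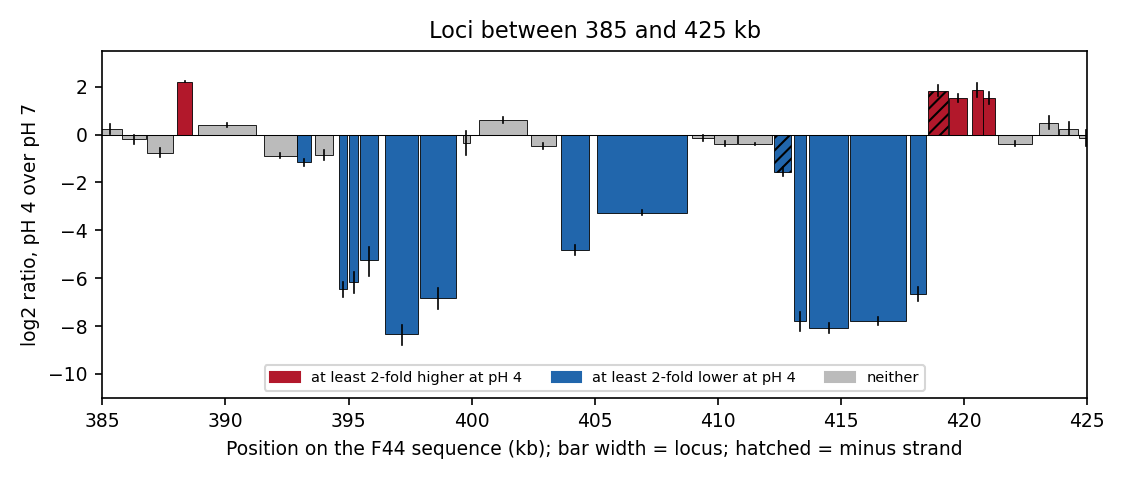
The 34 kept loci around the blocks at 394628 and 413106 on the F44 sequence (x axis, kb), with the log2 ratio of pH 4 over pH 7 on the y axis. Bars span each locus, hatched bars are on the minus strand, and black lines are 95% counting intervals. The blocks at 394628 to 399358 and 413106 to 418481 stand out as lower at pH 4, with 13 loci lower and 5 higher in the window drawn.

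Inside the duplicated segment, 25 of 80 kept loci were at least 2-fold higher at pH 4 and 24 were at least 2-fold lower, and blocks of both directions were present. The longest lower block, from 862764 to 879747, held 12 loci on the plus strand of the first copy with a summed log2 ratio of -5.07 (-5.20 to -4.95). Its members lay between -6.30 and -3.48. Another, from 903983 to 908329, held 3 loci with a log2 ratio of -7.77 (-8.02 to -7.54). The remaining lower block, of 4 loci from 851300 to 856691, had a log2 ratio of -1.31 (-1.71 to -0.94). Of the higher blocks, 3 plus-strand loci from 824737 to 827929 had a log2 ratio of 3.66 (3.51 to 3.82), and 5 from 896294 to 901267 had one of 2.12 (1.88 to 2.36). Reads of the copies cannot be told apart in these counts, so these values belong to the copies together.

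On the minus strand, a block of 8 loci from 2183010 to 2192786 had a log2 ratio of -4.43 (-4.50 to -4.36), with members between -5.63 and -1.36. A block of 7 loci from 1774579 to 1785445 had a log2 ratio of -3.09 (-3.14 to -3.04). At 1300589 to 1304740, 3 loci had a summed log2 ratio of -4.54 (-4.63 to -4.45). On the plus strand, 3 loci from 1785813 to 1789333 had a summed log2 ratio of -5.76 (-5.91 to -5.61), and 4 loci from 28449 to 34044 had one of -5.55 (-5.97 to -5.18). The block with the most members held 14 minus-strand loci from 2238106 to 2244613. The log2 ratios of these loci lay between -2.17 and -1.13, with a summed log2 ratio of -1.67 (-1.70 to -1.64). This block took 1.10% of the counts at pH 7 (1.09 to 1.12) and 0.357% at pH 4 (0.351 to 0.364).

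Loci that were higher at pH 4 formed 38 blocks of at least 3 loci, holding 138 of the 424 higher loci. The greatest gain of abundance was in 3 minus-strand loci from 1402529 to 1406242. They took 0.539% of the counts at pH 7 (0.530 to 0.549) and 1.65% at pH 4 (1.64 to 1.66), a log2 ratio of 1.57 (1.54 to 1.60). A block of 6 plus-strand loci from 311904 to 318210 took 0.284% at pH 7 (0.277 to 0.291) and 1.25% at pH 4 (1.23 to 1.26), a log2 ratio of 2.09 (2.05 to 2.13). The minus-strand block from 2206869 to 2210619, of 3 loci, had a log2 ratio of 3.17 (3.10 to 3.25), and its members lay between 1.45 and 3.74. The highest ratio of a block of at least 3 loci was 4.01 (3.59 to 4.48), in 3 less abundant plus-strand loci from 1891447 to 1893351 with 1072 counts at pH 4 and 45 at pH 7. Blocks at 479865 to 484126, 598664 to 603542 and 740524 to 744022 on the plus strand had log2 ratios of 1.34, 1.65 and 1.52. The block at 598664 lies inside a run of 10 loci, of which 4 were higher and 0 lower. The longest higher block held 8 plus-strand loci from 1254628 to 1261455, with a log2 ratio of 1.71 (1.65 to 1.78).

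Outside the duplicated segment, the highest ratio among loci of 1 model with at least median abundance was that of DYH_g0124. It is a coding region of 1182 bases at 136409 to 137590 on the minus strand. Its TPM was 17.3 at pH 7 and 496 at pH 4, a log2 ratio of 4.79 (4.41 to 5.21). Next was DYH_g0871, a coding region of 2433 bases at 941756 to 944188 on the plus strand. Its TPM was 14.6 at pH 7 and 291 at pH 4, a log2 ratio of 4.26 (3.98 to 4.57).

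The clustering of loci called the same way was compared with shuffled calls. Of 183 runs of at least 3 closely spaced same-strand loci, all members were lower at pH 4 in 22 and higher in 13. When the calls were shuffled 1000 times among loci of similar abundance, the highest numbers were 6 and 6. Members were called in opposite directions in 5 runs.

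**Figure D3:**
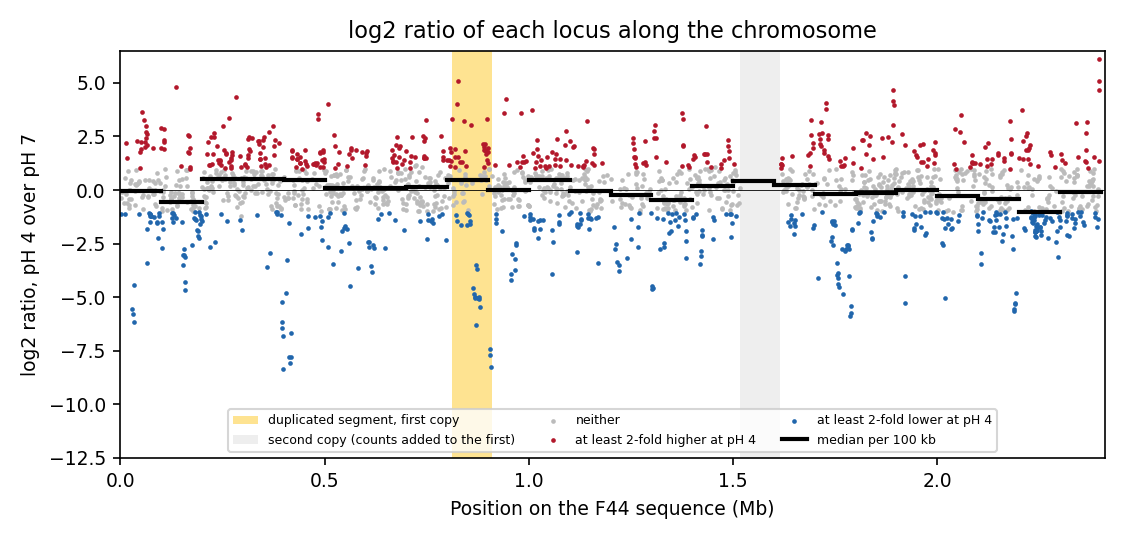
The log2 ratio of pH 4 over pH 7 for each locus (points, y axis) by its position on the F44 sequence in Mb (x axis), with the median per 100 kb as black lines. The shaded bands mark both copies of the duplicated segment, whose counts are shown at the first copy. Points under -5 include members of the lower blocks that start at 28449, 394628, 413106, 862764, 903983, 1785813 and 2183010.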

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

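The numbers of gene models higher and lower at pH 4 (465 and 473) stayed within 1.5 times of these values under the other scalings, filters and pseudocount and with the deposited TPM, where they ran from 444 to 548 and from 401 to 480. Upper-quartile scaling gave 548 and 401, and relative to TMM it moved ratios toward pH 4 by up to 0.15 on the log2 scale. A 4-fold threshold left 162 and 188 models, by construction. The authors' deposited fold changes, which cover only models with p under 0.05, gave 330 and 311. Of the 418 models past the authors' FDR of 0.05, 175 also passed 0.001 with at least a 2-fold difference. Chosen after the data were seen, summing overlapping models gave 445 and 451, counting the duplicated segment once gave 444 and 454, and both together gave 424 and 432. Of 72 ratios recomputed for the 4 named models and 14 blocks, 53 stayed within the counting interval and 19 did not. Most of these recomputations are other scalings, which shift every ratio alike by at most 0.15 on the log2 scale, so they could not reverse ratios of this size and do not test their stability. No paired analysis was possible because each condition has 1 library. Medians of the fixed gene lists were not run because no model could be matched to a name. Depth limits single models through the counting interval, and the spread between cultures is unknown at any depth.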

Other observations

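Ratios differed between stretches of the chromosome. Between 2200001 and 2300000, 46 of 92 loci were at least 2-fold lower at pH 4 and 15 were higher, with a median log2 ratio of -1.01. Blocks of 6, 6 and 14 adjacent minus-strand loci, between 2228757 and 2244613, held many of the lower loci. Neighbours share their ratios, so the loci of a stretch are not independent, and a position effect beyond such blocks was not tested. From 100001 to 200000 the median was -0.54, with 32 of 92 loci lower and 13 higher. In contrast, the medians were 0.53 from 200001 to 300000 and 0.53 from 300001 to 400000. In the duplicated segment, 25 of 80 kept loci were at least 2-fold higher and 24 at least 2-fold lower, together 61.3%, against 42.8% of the other 1884 loci. This difference was not tested, and blocks of 12, 4 and 3 neighbouring loci make up most of the lower loci there. It held 13 of the 51 loci that were at least 16-fold lower. Its loci had a median of 23.4 CPM at pH 7, with both copies summed, against 135 CPM for other loci.

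All tests in this part were chosen after the result was seen. The first pattern is a set of 29 gene models listed at 0 in 1 library and at 10 or more counts in the other, 15 at 0 at pH 4 and 14 at 0 at pH 7. Of these, 89.7% overlapped another model, against 6.01% of the other kept models, so reads of 1 locus divided differently between overlapping models are a candidate cause. A transcript made in only 1 of the 2 conditions is another candidate. Only 1 locus was still at 0 in 1 library once overlapping models were summed and the segment was counted once. Summing can only move a locus off 0, so this number alone does not decide it. All 20 of the largest fold changes in the authors' deposited table had under 0.5 counts in 1 library, and 19 belonged to overlapping models. Of the 29 models, 26 overlapped another and lay in 23 loci. The median absolute log2 ratio of these 26 models was 6.70, and that of the summed loci was 1.02. The models were chosen for a count of 0, so 6.70 depends on the pseudocount and a fall after summing is largely fixed by the choice. After summing, 10 of the 23 loci were within 2-fold, which argues against a transcript made in only 1 condition for those loci. The largest absolute log2 ratio of the 23 summed loci was 4.69, so part of the difference stays open.

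An example of overlapping models lies at 282460 to 283662 on the minus strand, where the authors' deposited table gives its largest log2 fold in favour of pH 4, 13.44. That model of 1203 bases held 1654 counts at pH 4 and 0 at pH 7, while a model of 1188 bases inside it held 812 and 81. Their sum, 2466 against 81, gives a log2 ratio of 4.36 (4.05 to 4.71). At 1755236 to 1756714, the authors' deposited table gives its largest log2 fold in favour of pH 7, 12.76 as pH 7 over pH 4. The sum of the models there gives a ratio in the same direction but smaller, -3.85 as pH 4 over pH 7 (-4.14 to -3.59).

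The second pattern is the mirrored segment. Reads shared between 2 copies of 1 sequence are a candidate cause of the equal counts, which held in 78 of 78 mirrored pairs. Equal counts also served to locate the segment, so this number is not an independent check. Whether the genome of F44 holds the segment in both places or the assembly lists it in error cannot be told apart here. With the CPM of each locus added over both libraries, the median of its loci was 0.233 of the median of other loci, while loci differed from each other with an SD of 2.36 on the log2 scale. RNA abundance varies too widely between loci to show how many copies the genome holds, so this value does not decide the question. Coverage of genomic DNA was not analysed here. Of the 418 models in the authors' significant table, 54 lie in the 2 copies of the segment, so a list by gene model counts its loci more than once.

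The third pattern is the likeness of neighbours, which gives a check within these 2 libraries in the absence of replicates. Same-strand neighbours up to 50 bases apart had ratios with r of 0.94 over 359 pairs. At over 100 and up to 300 bases, r was 0.486 over 582 pairs, above the highest of 1000 shuffles, 0.136, which argues against reads that span 2 neighbouring models as the whole cause. For neighbours up to 300 bases apart, r of same-strand pairs exceeded that of opposite-strand pairs by 0.505, against at most 0.209 in 1000 shuffles. The pairs were not matched for distance, so this difference mixes strand with distance. Same-strand pairs over 100 bases apart still had r of 0.486, against 0.188 over 281 opposite-strand pairs up to 300 bases apart. That comparison was not shuffled, but it argues against a regional trend alone. A hypothesis that stays open is that closely spaced same-strand loci are transcribed as 1 unit: r fell by 0.453 from the closest to the farthest same-strand pairs, against 0.1003 at the 95th percentile of shuffles. Reads that span neighbouring models would also make r fall with distance, so the fall does not separate these explanations. Genes are not independent replicates, and a difference between the cultures other than pH would give the same likeness.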
